A study of Mus musculus with 24 samples.

How the data were processed

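RNA of the striatum of C57BL/6J mice aged 6 to 10 weeks was hybridised to 24 Illumina mouse beadchip arrays. Per the labels, biotinylated cRNA was prepared from total RNA, and each array is 1 animal of 1 of 4 groups of 6: mice that had drunk saccharin or morphine over a long period, each killed 4 h after a last injection, which held either morphine at 20 mg/kg or saline in a volume of 10 ml/kg. Animal numbers in the sample titles differ between groups, so no number pairs animals. The array identifiers in the labels place the arrays on 6 chips. Each chip held 4 arrays, 1 of each group.

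The authors deposited a table of probe intensity on a linear scale, with no normalization between arrays. Whether the scanner software had subtracted background is not given in the sources used here. The authors also deposited a table of log2 values. Within each array these ranked the probes as the intensities did (rank correlation 1), and they lay within 0.0351 log2 units of quantile-normalized log2 intensities with no background step. They were not centred on 0, and the tool behind them is not given in the sources used here. They served as an alternative.

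The intensities were corrected for background by normexp with an offset of 50, quantile-normalized and put on the log2 scale in limma 3.58.1 under R 4.3.3. Detection p-values, planned for the background step and the filter, were not used here, and the fallback fixed beforehand was used: probes with a mean above the 40th percentile of all probes, a log2 intensity of 7.05, were kept. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none listed in the platform annotation, whose symbols were unchanged when looked up by Entrez number in the RefSeq gene table of assembly GRCm38.p6. Only probes with 1 symbol were tested, and the brightest stood for its gene where several passed. This left 13748 genes, of which 5650 had more than 1 probe above the filter. The annotation names no genome build, so no coordinates are given. The precision is limited by the number of arrays, and the standard error of a log2 difference between 2 groups had a median of 0.142.

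Each gene was fitted with lmFit and eBayes over all 24 arrays, with group and chip as fixed terms. The 6 contrasts were the acute response in saccharin drinkers and in morphine drinkers, morphine against saccharin drinking under each injection and averaged over injections, and the interaction. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 13748 genes of each comparison, with a threshold of 0.05. Gene lists were fixed before the data were examined. There were 27 lists with 691 entries, 572 of them tested, and the 26 lists with at least 5 tested members were compared with the other genes by camera with a preset correlation of 0.01 and again with an estimated correlation. Each list was also tested by fry against no change, without reference to the other genes. A list score is the mean log2 intensity of the tested members on 1 array, and within-chip differences of scores were tested by exact two-sided sign flips over 6 chips, which can give no p below 0.0313. Responses of the 2 kinds of drinkers were also compared on genes chosen on 3 chips and measured on the other 3, over 20 halvings.

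Named genes followed a rule fixed before the data were examined: for each comparison up to 10 rises and 10 falls of largest size that passed and had the same direction on at least 5 of 6 chips, up to 4 passing members per list, the 5 smallest p where fewer than 5 genes passed, and 16 landmark genes of opioid, dopamine, activity and glucocorticoid biology. Genes named outside it were chosen after their values were seen, and this is said where they appear. The landmark Oprm1 had a single probe with a mean log2 intensity of 6.41, below the filter, and was not tested.

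On data simulated from the real means and spreads of 13748 genes, the fit of the acute comparison in saccharin drinkers recovered 43 of 100 genes changed by 0.5 log2 units and 86 of 100 changed by 1, and 5.84% of its calls were unchanged genes. The interaction recovered 25 and 62 of 100, with 6.45% unchanged genes. The simulated noise was independent between genes and arrays, so these shares take no account of correlated genes or unusual arrays. Alternatives covered the background step, scaling, the authors' values, the filter, probes per gene, chip and chip position as blocks, the groups in the fit, array weights, the prior, and each array or chip left out. The alternative with detection p under 0.01 on all arrays was not run, and a filter at the 60th percentile, chosen after seeing the data, took its place. Scaling to a common median and cyclic loess followed the normexp step in place of the planned step with detection p-values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.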

Results

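The series set the effects of long-term morphine drinking beside those of a morphine injection in the mouse striatum, a forebrain region made up mostly of medium spiny neurons. Morphine, an opioid agonist, or saccharin, a sweetener given as the control drink, was taken orally, and 4 groups of 6 mice were compared 4 h after an injection of morphine or saline. Median raw intensity ranged from 164 to 543 over the 24 arrays and differed mainly between chips, from 164 to 177 on chip 6 and from 307 to 543 on chip 1. After normalization, pairs of arrays correlated at 0.937 to 0.993 across the 13748 genes tested. Values are log2 intensities as mean ± SD (n = 6 arrays per group) or log2 differences with their standard error (SE).

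On 2 arrays of morphine drinkers on chip 2, 1 from each injection, the genes of medium spiny neurons were far lower than elsewhere. The mean over 26 such genes was 9.66 on replicate 32 (saline) and 9.60 on replicate 31 (morphine), against 11.8 to 12.6 on the other 22 arrays. The D1 dopamine receptor gene Drd1 stood at 10.07 and 9.83, and the D2 receptor gene Drd2 at 7.69 and 7.08. Neurod2, a transcription factor gene of cortical excitatory neurons, stood at 12.48 and 13.08, and Fezf2, a marker of deep-layer cortical projection neurons, at 12.29 and 12.48. Neurod2 and Fezf2 were chosen after their values were seen. For comparisons that touch morphine drinkers, an alternative chosen after seeing the data leaves these 2 arrays out. Its values are given for the number of genes called, for the gene lists named where they turned sign, changed a call or moved over 1.5 times, and for some genes.

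**Figure D1:**
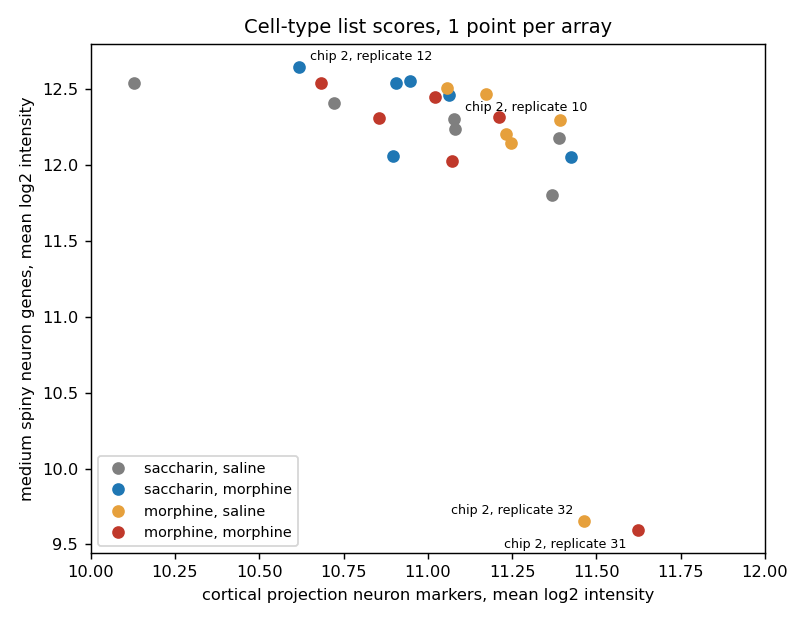
Mean log2 intensity per array of medium spiny neuron genes (vertical) against cortical projection neuron markers (horizontal), 1 point per array, coloured by drink and injection, with the chip 2 arrays marked. Replicates 32 and 31 lie at 9.66 and 9.60 on the vertical axis, below the other 22 arrays.

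The first comparison asked how a morphine injection changed the striatum of mice that had drunk saccharin. Genes induced by glucocorticoid hormones rose as a group. Plin4, which encodes a lipid droplet coat protein, rose 8.44-fold, from 8.34 ± 0.451 to 11.42 ± 0.351 (log2 change 3.08, SE 0.229, adjusted p = 1.26e-06 by limma). Tsc22d3, the glucocorticoid-induced leucine zipper, rose 2.13-fold, Fkbp5, a co-chaperone of the glucocorticoid receptor, 1.96-fold, and the kinase gene Sgk1 2.28-fold. Of 39 tested members of the glucocorticoid list, 17 rose, none fell, and 28 rose when adjusted over the list alone.

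In all, 41 genes rose and 10 fell, and every one of the falls and 40 of the rises had the same direction on 6 of 6 chips. The genes were called on these same chips, so the shared direction is no separate test. Further rises included Hif3a, a subunit of a hypoxia-inducible factor (2.76-fold), the cell cycle inhibitor Cdkn1a (2.36-fold), Xdh, which makes uric acid (2.27-fold), Sult1a1, a sulfotransferase (2.11-fold), and Map3k6, a stress kinase (2.08-fold). Angptl4, a secreted inhibitor of lipoprotein lipase, rose 2.11-fold, Mfsd2a, a lipid transporter of the blood-brain barrier, 1.98-fold, and the glucose transporter gene Slc2a1 1.63-fold. The falls included 2 transcription factor genes of the oligodendrocyte lineage, Nkx2-2 (log2 change -0.82, SE 0.120, adjusted p = 0.00381) and Sox10 (-0.55, SE 0.0856, adjusted p = 0.00686). Cyp2e1, a cytochrome P450 gene, changed by -0.87 and the transcription factor gene Sox21 by -0.81. After the morphine injection Cyp2e1 had a mean of 6.93, below the filter of 7.05. The fatty acid elongase gene Elovl6 changed by -0.47. Plekho2 (-0.67), Gkn3 (-0.59), Trim59 (-0.57), Fastkd1 (-0.54) and Pdzrn4 (-0.42) completed the falls. Named genes that passed had 16 further probes above the filter, 14 of the same sign, 8 of these with an unadjusted p under 0.05, and the opposite signs (a dim Nkx2-2 probe at 0.10 and a Fastkd1 probe at 0.24) had no unadjusted p under 0.05. Some of the same sign were far weaker, as for Pdzrn4 (-0.02 and -0.11, against -0.42 for the probe used), Hif3a (0.12 and 0.33, against 1.47) and a dim Tsc22d3 probe (0.19, against 1.09).

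The glucocorticoid list was shifted upward as a whole (median 0.55, adjusted p = 1.55e-51 by camera, 1.19e-04 with an estimated correlation), and its score rose on 6 of 6 chips by 0.66 ± 0.139 (SD over chips, exact p = 0.0313, the smallest possible; 0.325 after adjustment over 26 lists). Another 3 lists were called downward by camera and lost the call. Immediate-early genes, which mark recent neuronal activity, had a median of -0.22 (adjusted p = 2.02e-04; adjusted p = 0.438 with an estimated correlation), with none of 20 past the threshold and 5 falling when adjusted over the list alone. Fos, among them, differed by -0.90 (SE 0.311, adjusted p = 0.461) and Arc by -0.42 (adjusted p = 0.752), and neither passed. Mitochondrial respiratory chain genes had a median of -0.06 (adjusted p = 0.00918; adjusted p = 0.575 with an estimated correlation). The 24 myelin and oligodendrocyte markers had a median of -0.05, with Sox10 past the threshold and 4 falling and 1 rising when adjusted over the list alone (adjusted p = 0.00918; adjusted p = 0.575 with an estimated correlation). The other 22 lists were not called, the opioid peptide and receptor list (median -0.02, adjusted p = 0.432) and astrocyte markers (median 0.03, adjusted p = 0.700) among them. Fasting and fatty acid oxidation genes, also not called, had a score that was higher on 6 of 6 chips by 0.15 ± 0.100 (exact p = 0.0313; 0.325 after adjustment). The landmarks Pdk4 (0.69, adjusted p = 0.213), Pdyn (0.34), Drd2 (0.19), Drd1 (0.12), Penk (0.12), Per1 (0.05) and Gfap (-0.09) did not pass, the last 6 with adjusted p of 0.868 to 0.977. Pdk4 passed once the 2 chip 2 arrays were left out (adjusted p = 0.0424 by limma), which moves the shared spread. In that fit camera called 10 lists here, fasting and fatty acid oxidation genes among them (adjusted p = 0.0466, and 0.396 with an estimated correlation).

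The count of 51 genes was 28 without the chip as a block, 30 with chip position added, 10 after scaling to a common median and 10 when only these 2 groups were fitted, and lay between 12 and 51 with 1 array or chip left out. Over 46 alternative settings Plin4, Tsc22d3, Fkbp5, Sult1a1 and Mfsd2a passed in all, while Elovl6, Trim59, Gkn3 and Pdzrn4 missed the threshold in 32, 33, 34 and 34. Fastkd1 missed it in 20, and Cyp2e1 in 20 of the 45 in which it was tested.

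**Figure D2:**
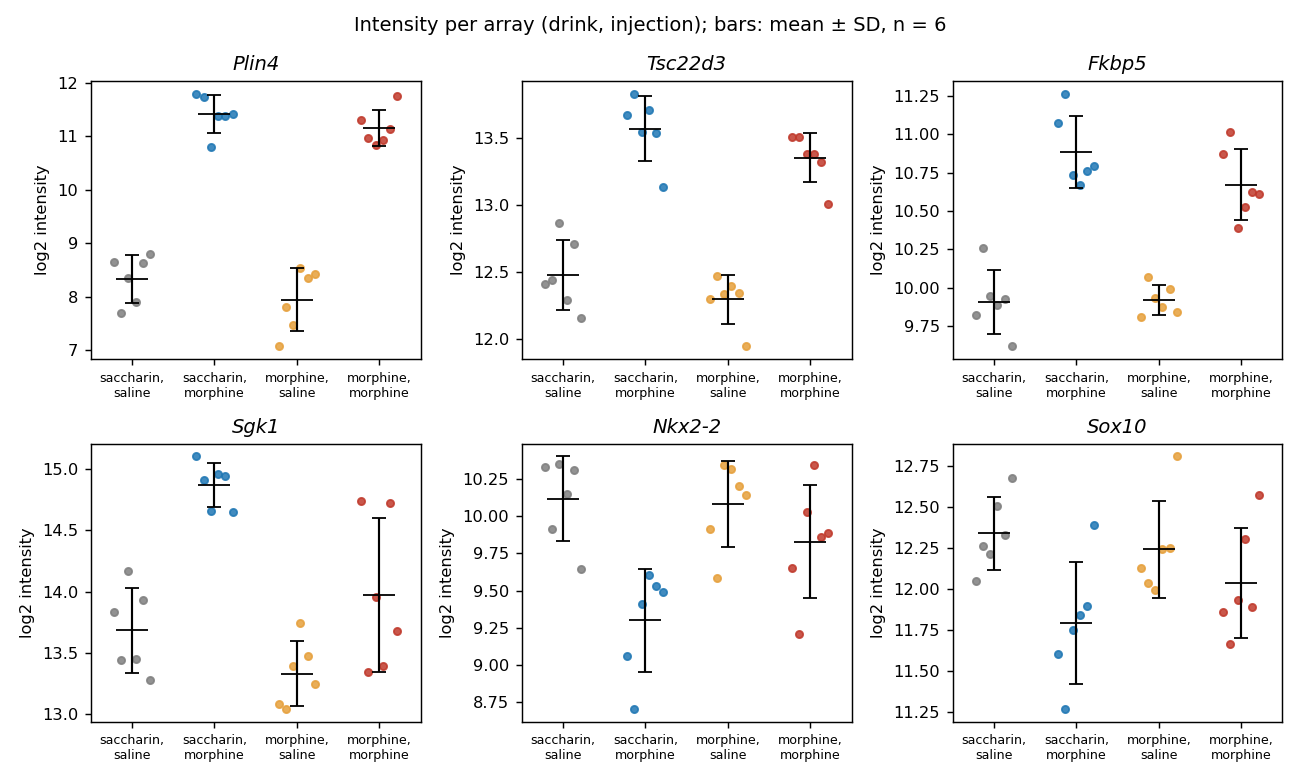
Log2 intensity per array of 6 named genes by drink and injection, points for arrays and bars for mean ± SD (n = 6). Plin4 lies between 10.8 and 11.8 on the morphine-injected arrays and at or below 8.80 on the saline arrays.

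The second comparison put the same injection to mice that had drunk morphine. Plin4 rose 9.24-fold, from 7.95 ± 0.594 to 11.15 ± 0.335 (log2 change 3.21, SE 0.229, adjusted p = 6.40e-07 by limma). Hif3a rose 2.35-fold, Tsc22d3 2.07-fold, Mfsd2a 2.04-fold, Sult1a1 1.89-fold and Fkbp5 1.68-fold. Gjb6, which encodes the astrocyte gap junction protein connexin 30, rose 1.61-fold, the adiponectin receptor gene Adipor2 1.49-fold and the receptor kinase gene Mertk 1.44-fold. These 9 genes rose on 6 of 6 chips, the same chips on which they were called, and no gene fell. Of 6 further probes of these genes 3 had an unadjusted p under 0.05 and 5 the same sign, and a dim Hif3a probe had the opposite one (-0.10). The 2 further probes of Adipor2 were at 0.08 and 0.00, against 0.57 for the probe used. Of the 39 glucocorticoid list members 8 rose, and 22 rose when adjusted over the list alone.

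The glucocorticoid list was called upward (median 0.39, adjusted p = 3.80e-35 by camera, 0.00103 with an estimated correlation), and its score rose on 6 of 6 chips by 0.49 ± 0.204 (exact p = 0.0313; 0.305 after adjustment). Sgk1 (0.64, adjusted p = 0.398), Cdkn1a (0.77, adjusted p = 0.309) and Pdk4 (0.39, adjusted p = 0.783) did not pass here. Fos differed by -0.01, Arc by 0.17, Per1 by 0.21, Pdyn by 0.15, Penk by -0.02, Drd1 by -0.07, Drd2 by -0.15 and Gfap by 0.13, with adjusted p of 0.903 to 0.999, and without the 2 chip 2 arrays Arc was at 0.02, Penk at 0.03 and Gfap at 0.35. A further 5 lists were called by camera and lost the call. Respiratory chain genes had a median of 0.06 (adjusted p = 0.586 with an estimated correlation) and activity-regulated neuronal genes of 0.17 (adjusted p = 0.583 with an estimated correlation). Microglia markers had a median of -0.07 (adjusted p = 0.586 with an estimated correlation), blood cell markers of -0.32 (adjusted p = 0.583 with an estimated correlation) and cortical projection neuron markers of -0.15 (adjusted p = 0.586 with an estimated correlation). Leaving out the 2 chip 2 arrays moved these medians to 0.05, -0.25 and -0.25, and of these and the respiratory chain genes only the cortical markers stayed called by camera. The other 20 lists were not called, although interferon response genes, at -0.06, were at 0.25 and called without those arrays (adjusted p = 0.614 with an estimated correlation).

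Without the 2 chip 2 arrays, 12 genes rose, 8 of the 9 among them, Gjb6 did not pass (0.69, adjusted p = 0.0667), and in saccharin drinkers, where the refit moves the shared spread, 60 genes passed, 48 of the 51 among them. The count of 9 was 63 (40 rises and 23 falls) with array weights, 18 with a trended and robust prior, 5 after scaling to a common median, 2 when only these 2 groups were fitted and 5 to 13 with 1 array or chip left out, and over 46 settings Gjb6 missed the threshold in 25, Hif3a in 14, Mertk in 7 and Adipor2 in 4.

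**Figure D3:**
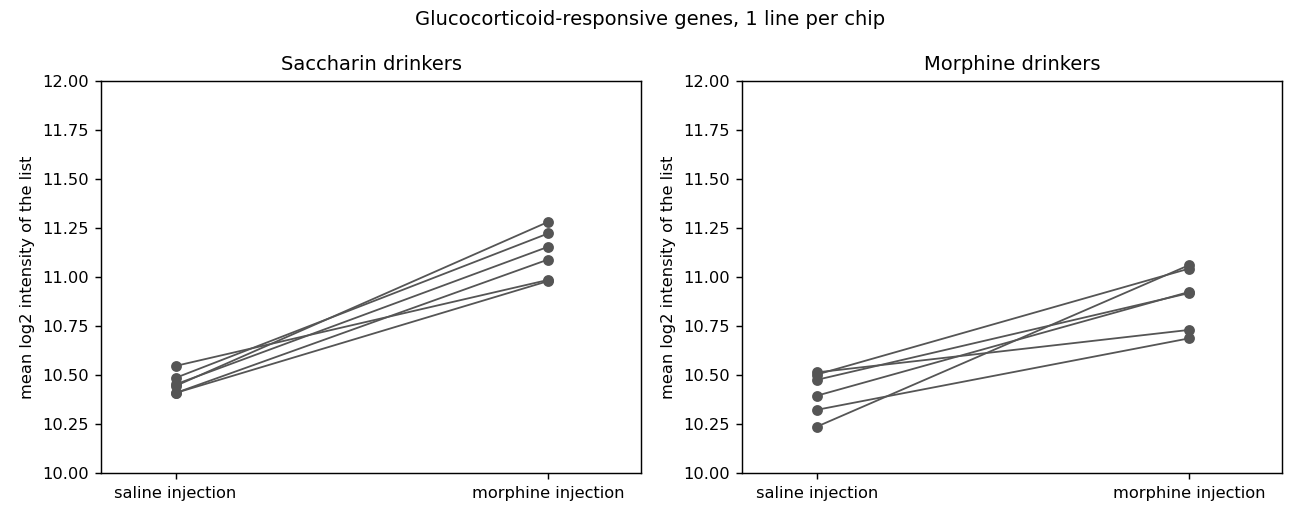
Mean log2 intensity of 39 glucocorticoid-responsive genes under saline and morphine injection, 1 line per chip, for saccharin drinkers (left) and morphine drinkers (right). All 12 lines rise, by a mean of 0.66 on the left and 0.49 on the right.

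Both kinds of drinkers shared their leading genes. In both comparisons 8 genes passed, Plin4, Tsc22d3, Fkbp5, Sult1a1, Mfsd2a, Hif3a, Mertk and Adipor2, where 0.0334 would be expected of independent lists. The 2 comparisons have no arrays in common but share the estimated spread of each gene. The lists are therefore not fully independent, and 0.0334 is only a rough guide. Without the 2 chip 2 arrays 11 passed in both. All 51 genes called in saccharin drinkers had the same sign in morphine drinkers, and 41 of them had an unadjusted p under 0.05 there. The mean change of the glucocorticoid list was 0.66 and 0.49, and 29 of its 39 members had the smaller rise in morphine drinkers. Genes chosen in saccharin drinkers on 3 chips moved in the chosen direction on the other chips by a median of 0.34 in saccharin and 0.27 in morphine drinkers. The median ratio was 0.78 over 20 halvings (range 0.42 to 2.28), and it was under 1 in 15. Across all 13748 genes the fold changes correlated at r = 0.142, and at 0.110 without the 2 chip 2 arrays, 0.0403 without chip 2, 0.0851 without chip 6 and 0.268 with the filter at the 60th percentile, and genes are not independent replicates.

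**Figure D4:**
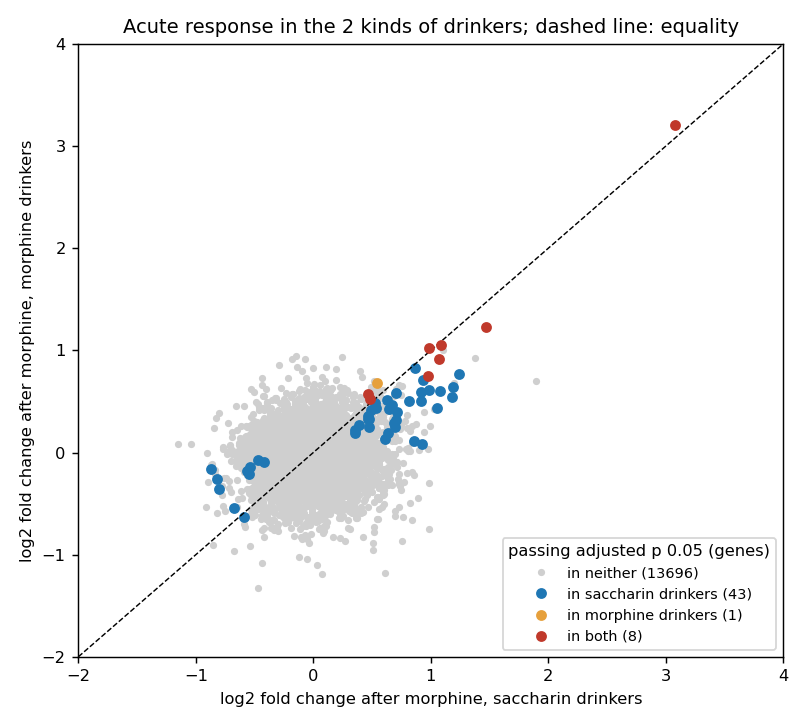
Log2 fold change after the morphine injection in morphine drinkers (vertical) against saccharin drinkers (horizontal), 1 point per gene, coloured by the comparison in which adjusted p was under 0.05. The 8 genes passing in both lie in the upper right, Plin4 at 3.08 and 3.21.

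Whether the acute response differed between drinkers was tested by the interaction. No gene passed. Snx24, a sorting nexin gene that rose in saccharin drinkers, differed by -0.48 (SE 0.110), Taar8b, a trace amine receptor gene, by -1.62 (SE 0.360), the vesicle transport gene Arf4 by -1.04 (SE 0.237), Ccdc85b by 0.44 and Klhdc9 by -0.84, all with adjusted p = 0.935. Taar8b and Arf4 lay near the filter of 7.05, with group means of 6.72 to 7.60 and 6.86 to 7.59. Among the genes above, the interaction was -0.55 for Sgk1 (adjusted p = 0.942), -0.22 for Fkbp5 (0.944), -0.46 for Cdkn1a (0.958), 0.13 for Plin4 (0.994), -0.04 for Tsc22d3 (0.995) and 0.89 for Fos (0.942). The glucocorticoid score differed by -0.17 ± 0.214 over chips, lower in morphine drinkers on 5 of 6 (exact p = 0.125). The score of activity-regulated neuronal genes differed by 0.16 ± 0.175 and was higher on 6 of 6 (exact p = 0.0313; 0.609 after adjustment).

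On the interaction 4 lists were called by camera, and none with an estimated correlation. The glucocorticoid list had a median of -0.18 (adjusted p = 6.72e-04; adjusted p = 0.548 with an estimated correlation) and immediate-early genes of 0.24 (adjusted p = 0.486 with an estimated correlation). Respiratory chain genes had a median of 0.12 (adjusted p = 0.387 with an estimated correlation) and blood cell markers of -0.56 (adjusted p = 0.387 with an estimated correlation). Leaving out the 2 chip 2 arrays moved the blood cell median to -0.42, which was no longer called. Interferon response genes (0.45, against 0.13 with all arrays) and medium spiny neuron genes (-0.15, against -0.17) were called only then (adjusted p = 0.558 and 0.805 with an estimated correlation). By limma 723 genes had an unadjusted p under 0.05, against 687.4 expected by chance, and each alternative run also called 0. The median of all genes in this comparison was 0.101 under scaling to a common median, against 0.00294 here.

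Morphine and saccharin drinkers were then compared under saline. No gene passed. The smallest p-values belonged to Nlgn1, a synaptic adhesion gene (7.92 ± 0.306 in saccharin and 8.80 ± 0.510 in morphine drinkers, log2 difference 0.88, adjusted p = 0.495), Bend3 (0.54), Anapc10, a subunit of a ubiquitin ligase (-0.47), Stra6, a retinol transporter (0.74), and Slc6a11, a GABA transporter (-0.48), the last 4 with adjusted p = 0.986. Fos differed by -0.69 and Sgk1 by -0.35, and neither passed (adjusted p = 0.986). Fos stood at 11.12 in saccharin drinkers given saline and at 10.21 to 10.42 in the other groups. Its differences here, in the first comparison and in the interaction thus rest on the same arrays. Medium spiny neuron genes had a median of -0.35 and cortical projection neuron markers of 0.27, and both were called by camera (adjusted p = 0.615 and 0.497 with an estimated correlation). Without the 2 chip 2 arrays these medians were 0.13 and 0.23, the first with its sign turned. Both were called by camera with the preset correlation only. Thalamic, septal and hypothalamic markers were called only without these arrays (median -0.26, adjusted p = 0.813 with an estimated correlation).

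Another 7 lists were called under saline, and none held with an estimated correlation. Immediate-early genes had a median of -0.30 (adjusted p = 0.324 with an estimated correlation), activity-regulated genes of -0.18 (adjusted p = 0.324 with an estimated correlation) and GABA signalling genes of -0.14 (adjusted p = 0.324 with an estimated correlation). The last 2 were at -0.07 and -0.06 without the 2 chip 2 arrays and were then not called. Interferon response genes had a median of 0.17 (adjusted p = 0.615 with an estimated correlation), which was -0.04 without those arrays. The medians were 0.16 for inflammatory cytokine genes (adjusted p = 0.497 with an estimated correlation), 0.11 for microglia markers (adjusted p = 0.613 with an estimated correlation) and -0.03 for respiratory chain genes (adjusted p = 0.613 with an estimated correlation). These 3 lists stood at 0.01, 0.05 and -0.03 without those arrays, and none was then called. By limma 633 genes had an unadjusted p under 0.05, against 687.4 by chance, and each alternative run also called 0.

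Under the morphine injection, again no gene passed between morphine and saccharin drinkers. This comparison shares its 6 saccharin arrays with the first comparison, so it is no independent test of the genes that rose or fell there. Sgk1 differed by -0.90 (14.87 ± 0.179 in saccharin and 13.97 ± 0.629 in morphine drinkers), Depp1 by -0.83, Angptl4 by -0.77, Errfi1 by -0.39 and Nkx2-2 by 0.53, each with adjusted p = 0.868. The glucocorticoid list had a median of -0.18 (adjusted p = 1.49e-09; adjusted p = 0.250 with an estimated correlation), with 9 members lower when adjusted over the list alone. Its score was lower on 6 of 6 chips by a mean of -0.22 ± 0.133 (exact p = 0.0313; 0.271 after adjustment), and after scaling to a common median by -0.12 (exact p = 0.313). The median of all genes was 0.0877 under that scaling, against 0.00743 here.

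Medium spiny neuron genes had a median of -0.52 here (adjusted p = 0.786 with an estimated correlation), and of -0.02 without the 2 chip 2 arrays. Interferon response genes had a median of 0.29 with 20 of 20 positive (adjusted p = 0.786 with an estimated correlation), and of 0.37 without those arrays. Respiratory chain genes had a median of 0.08 (adjusted p = 0.346 with an estimated correlation). The scores of these 2 lists were higher on 6 of 6 chips, by 0.31 ± 0.287 and 0.08 ± 0.0573 (exact p = 0.0313 and 0.271 after adjustment for each). Medians were also negative for fasting and fatty acid oxidation genes, at -0.10 (adjusted p = 0.346 with an estimated correlation), and positive for vesicle and cytoskeletal genes, at 0.12 (adjusted p = 0.717 with an estimated correlation). Neither was called without those arrays, at -0.03 and 0.05. By limma 758 genes had an unadjusted p under 0.05, against 687.4 by chance. Alternatives called 0, except that 1 gene passed without replicate 34 of the morphine drinkers given morphine, and 1 without chip 3.

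Averaged over both injections, 12 arrays against 12, no gene passed. Nlgn1 (0.59), Bend3 (0.40) and Kifbp (0.33) were higher and Sgk1 (-0.63) and Angptl4 (-0.53) lower in morphine drinkers, with adjusted p = 0.622 for each. Drd1 differed by -0.61 (SE 0.368), Drd2 by -0.67 (SE 0.422), Penk by -0.35 and Pdyn by -0.42, and none passed (adjusted p of 0.904 to 0.906). Without the 2 chip 2 arrays these genes were at 0.05, 0.08, 0.24 and 0.01. Medium spiny neuron genes had a median of -0.42 (adjusted p = 0.498 with an estimated correlation), and of 0.06 without those arrays. The glucocorticoid list had a median of -0.11 (adjusted p = 0.294 with an estimated correlation), and of -0.11 without those arrays. Its score was lower on 6 of 6 chips by a mean of -0.14 ± 0.0925 (exact p = 0.0313; 0.406 after adjustment), and that of fasting and fatty acid oxidation genes by -0.11 ± 0.142 (exact p = 0.0313; 0.406 after adjustment).

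Interferon response genes had a median of 0.23 in the averaged comparison (adjusted p = 0.498 with an estimated correlation) and immediate-early genes of -0.17 (adjusted p = 0.498 with an estimated correlation). Fasting and fatty acid oxidation genes had a median of -0.08 (adjusted p = 0.294 with an estimated correlation), vesicle and cytoskeletal genes of 0.06 (adjusted p = 0.498 with an estimated correlation), microglia markers of 0.05 (adjusted p = 0.585 with an estimated correlation) and cortical markers of 0.18 (adjusted p = 0.498 with an estimated correlation). Leaving out the 2 chip 2 arrays moved the immediate-early median to -0.09, the fasting median to -0.07, the vesicle median to 0.01 and the cortical median to 0.05, and none of these 4 was then called. By limma 722 genes had an unadjusted p under 0.05, against 687.4 by chance, and each alternative run also called 0.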

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

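The tests of a chip fault and of a smaller response, the counts on 5 chips, and the fits without the 2 chip 2 arrays were chosen only after the results they bear on were seen. Outliers are given by the gap of the outermost array to its nearest neighbour over the range of its group. Of 204 groups of 6 values 18 passed Dixon's limit, where 10.2 would be expected by chance, and 11 of the 18 were replicates 32 and 31 on chip 2.

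Replicate 32 (morphine drinkers, saline) and replicate 31 (morphine drinkers, morphine) lay far below their groups for the medium spiny neuron list (ratios 0.874 and 0.826), Drd1 (0.772 and 0.814), Drd2 (0.838 and 0.771) and Penk (0.787 and 0.776). Replicate 31 was also low for Pdyn (0.743). Replicate 32 was high for the astrocyte genes Gfap (0.759; 13.7 against 11.11 to 11.74) and Gjb6 (0.749). The other outliers were Arf4 in replicate 9 of the saccharin drinkers given morphine (0.779), Fos in replicate 5 (0.669) and Pdyn and Penk in replicate 8 (0.641 and 0.765) of those given saline, and Fastkd1, Sox10 and Tsc22d3 in replicate 41 of the morphine drinkers given saline (0.708, 0.688 and 0.666).

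Medium spiny neuron genes were lower in morphine drinkers by a median of -0.42 averaged over injections. A fault of chip 2 that lowered these genes on all its arrays is argued against by its saccharin arrays. The lower of these, replicate 10 (saline), scored 12.3 against 11.8 for the lowest saccharin array elsewhere. Replicate 10 was itself unusual, with the lowest median correlation with other arrays (0.952) and the lowest array weight (0.230). Other faults of chip 2 are thus not excluded. Without replicates 32 and 31 the median was 0.0604, so the difference rested on these arrays. A candidate explanation is that they hold tissue other than striatum, such as cortex: their cortical marker scores were 11.46 and 11.62 against at most 11.42 elsewhere, over 19 tested markers of which 4 are in other lists, and all 19 lie above the filter in these samples. Neurod2 stood at 12.48 and 13.08 on these arrays, against at most 11.45 elsewhere. Fezf2 stood at 12.29 and 12.48, against at most 11.99, and both genes were chosen after their values were seen. A loss of medium spiny neuron transcripts alone would not raise cortical genes, so the values of these 2 genes argue against it. The marker scores add little, since the 11.46 of replicate 32 lay close to the 11.42 found elsewhere. The test shows which arrays carry the difference and not which tissue they hold.

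Fewer genes passed after the injection in morphine drinkers (9) than in saccharin drinkers (51). Without replicates 32 and 31, 12 passed, short of the 26 set beforehand, a bound that was wrong because it took no account of the chip lost with them. By the rule set for it, replicates 32 and 31 as the whole cause cannot be told apart from other causes. With 1 chip left out of the saccharin groups instead, these gave 11 to 39 genes, which takes in 12. Those fits still hold replicates 32 and 31 in the shared spread. With both left out, saccharin drinkers gave 20 to 49 genes and morphine drinkers 8 to 13, with more in saccharin drinkers in all 6 fits. These fits of equal size argue against replicates 32 and 31 as the whole cause, although the fits share most of their arrays. A smaller response in morphine drinkers was tested on held-out chips, where the median ratio was 0.782 and 15 of 20 halvings were under 1, short of the 19 set for it. It cannot be told apart from an equal response by that rule. The ratio ranged from 0.42 to 2.28, but the halvings overlap, so this range does not measure the error of the ratio. The 2.28 came from a halving in which saccharin drinkers moved by only 0.12, and the next highest ratio was 1.08. Every halving includes replicates 32 and 31.

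Between the 2 kinds of drinkers, 4 lists differed in their acute response by camera with a preset correlation: the glucocorticoid list (median -0.180), immediate-early genes (0.240), respiratory chain genes (0.119) and blood cell markers (-0.555). None was called with an estimated correlation.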

How the results depend on the processing

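Chosen after seeing the data were the fits without the 2 chip 2 arrays (and without a further saccharin array), the 60th percentile filter, the offset of 16, and scores and agreement without chip 2. Replicate numbers are not shared between groups and pair nothing, and the chip is the block. Not run were the detection p filters, for the counts and for the agreement. Of 31 results for named genes past the threshold, 1129 of 1425 values under alternatives stayed past it, 296 did not and none reversed. Of 98 results not past it, 5 values passed. In saccharin drinkers the 51 genes became 10 with scaling to a common median, 28 without the chip block, 30 with chip and position, and 10 with only the 2 groups, which leaves fewer arrays for the spread. In morphine drinkers the 9 became 5 with median scaling, 2 with only the 2 groups, 63 with array weights (0.230 to 3.60) and 18 with a trended and robust prior. Leaving out 1 array or chip gave 12 to 51 in saccharin drinkers, and fewer arrays alone lower such counts: 23, 27, 28 and 27 without replicates 1, 10, 3 and 5 (saline), 26, 30 and 31 without 11, 12 and 7 (morphine), and 16, 27, 15, 12 and 15 without chips 1, 3, 4, 5 and 6. It gave 5 (without chip 1) to 13 in morphine drinkers, and 0 to 1 between drinkers under morphine (1 without replicate 34 or chip 3). Camera's 4, 6, 9, 6, 8 and 4 lists, in the order saccharin drinkers, morphine drinkers, drink under saline, drink under morphine, averaged, interaction, became 1, 1, 0, 0, 0 and 0 with an estimated correlation, and fry, which tests a list against no change, called the same numbers. Without the 2 arrays they were 10, 4, 3 and 3 for saccharin drinkers and the 3 comparisons of drink. Without chip 2 the glucocorticoid score differences were 0.626, 0.496 and, between drinkers under morphine, -0.197, each with exact p = 0.0625, the smallest that 5 chips allow; the last was -0.123 with median scaling. The correlation across genes was 0.268 at the 60th percentile, and 0.0403 (without chip 2) to 0.162 with 1 chip left out, with 0.0851 without chip 6. Except where the construction is named, the cause was not tested. Signal over background limits dim genes such as Oprm1.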

Other observations

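The acute response averaged over both kinds of drinkers, and the test of oligodendrocyte-lineage cells, were chosen only after the results were seen, as were the genes named here. With 12 arrays against 12, 71 genes rose and 24 fell by limma, 48 of them in neither comparison alone, and without the 2 chip 2 arrays 79 rose and 19 fell, 81 of them also called with all arrays. Fgfr2, a fibroblast growth factor receptor gene, changed by -0.38 (adjusted p = 0.00183), the myelin gene Opalin by -0.65 (adjusted p = 0.00722), the microglial receptor gene Cx3cr1 by -0.49 (adjusted p = 0.00976) and the chemokine gene Cxcl12 by -0.58 (adjusted p = 0.0111). Zbtb16, a transcription factor gene, rose by 0.69 (adjusted p = 0.00736) and the clock gene Per2 by 0.43 (adjusted p = 0.0332). Of the 39 glucocorticoid list members 20 rose, and 28 when adjusted over the list alone (median 0.48, adjusted p = 4.16e-05 with an estimated correlation). Circadian clock genes (median 0.09), immediate-early genes (-0.12) and myelin markers (-0.01) were called by camera, each with adjusted p = 0.703 with an estimated correlation.

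Sox10 and Nkx2-2 fell after the injection in saccharin drinkers. Fewer oligodendrocyte-lineage cells of all kinds would lower their markers alike. The median over 24 myelin and oligodendrocyte markers was -0.0536 (quartiles -0.232 to 0.00889), far from the -0.55 of Sox10. The median over 11 oligodendrocyte precursor markers was -0.0331 (quartiles -0.180 to 0.132). A median cannot exclude fewer cells of some kinds. Averaged over drinkers, 7 of the 24 markers fell and 1 rose when adjusted over the list alone. A lower transcript level of Sox10 and Nkx2-2 within such cells may also remain as a hypothesis, and no test here bears on it.

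Regroupings of the arrays bear on whether chance can be excluded. In saccharin drinkers 2 of 100 splits, the real one included, gave at least the real 51 genes. The other gave 177, none of them among the 51, and so large a count points to a structure of the samples, whose nature was not tested. Without the 2 chip 2 arrays of morphine drinkers, which enter the fit, that split gave 6 and the real labels 60, a refit chosen after its count was seen. Exchanging labels within chips, 1 of 32 did so and the highest other was 0. In morphine drinkers it was 1 of 100 and 1 of 32 (real 9, highest other 1 in both). For both acute counts these shares were under the 0.05 set beforehand, with no adjustment over the 6 comparisons. A share of 1 of 32 is the smallest that the exchanges can give. The split with 177 genes shows that a grouping other than the labels can give more genes, so chance is not fully excluded. The 4 comparisons with a real count of 0 cannot exclude chance, since every regrouping gives at least 0. Under saline these were 100 of 100 and 32 of 32 (highest other 1, and 0 within chips), and under morphine 100 of 100 and 32 of 32 (2 and 1). For the average they were 100 of 100 in both (4 and 0), and for the interaction 100 of 100 in both (10 and 13).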
